A study of Mus musculus with 8 samples.

How the data were processed

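RNA from mouse brain was sequenced in 4 samples labelled as brain arteriovenous malformation (AVM) and 4 labelled control. Per the labels' protocols, RNA was extracted with TRIzol, enriched for messenger RNA, made into strand-specific libraries by dUTP incorporation and read as paired ends of 150 bases. They name poly(A) selection for eukaryotes and rRNA depletion for prokaryotes, so poly(A) selection was taken to apply here. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. The deposited gene counts are whole numbers, not normalized, with 1 column per sample and no pooled columns. The deposited FPKM values were made by the authors from those counts: within rounding, each value equals its count divided by the gene length in the file and by a single divisor per sample. That divisor was 1.0068 times the library size scaled by median-of-ratios factors in each of the 8 samples. The table holds 54532 genes, each with a name, mm10 coordinates and a biotype; 54495 of their identifiers are in GENCODE release M21 and 53585 have the same start and end there. Coordinates are printed as in the deposited file.

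Some limits come from the counting. Gapdh, a gene with many processed pseudogene copies, had a mean of 5 CPM in AVM and 13.4 CPM in control brain, while Actb had 829 and 740 CPM. Control 4 alone carried that gap in Gapdh, with 38.4 CPM against 3.35 to 7.19 CPM in the other 7 libraries; without it the control mean was 5.12 CPM. Reads that match several places may thus have been left out, and values of genes with near-identical copies (haemoglobin, ribosomal and mitochondrial genes with nuclear copies) are uncertain. Without a stated strand setting, reads of overlapping and antisense genes cannot be assigned with certainty.

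Groups were taken from the treatment label and replicate numbers from the sample titles. Differences were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts: genes were kept with filterByExpr defaults (16508 of the 30959 genes with any count), library sizes were scaled by TMM, and a quasi-likelihood model with the group as its only term was fitted to all 8 samples. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05 and no threshold on fold. The standard error of a log2 fold change was the estimate divided by the square root of its F value. CPM values use TMM library sizes. Exceptions are the summed haemoglobin CPM and the CPM of a single read or of 3 reads, which use total counts. Shares of counts, depth and the region score were compared by exact two-sided permutation tests over 70 arrangements, whose smallest p is 0.0286. Exchanges within the same-numbered pairs make 16 arrangements, whose smallest p is 0.125, so they cannot pass 0.05. Intervals for shares and read ratios are 95% Clopper-Pearson intervals and, like the floor of 3 counts for genes with no read, cover counting error only.

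A total of 65 gene lists (cell types, states, pathways, brain regions and technical groups) were written before the data were examined. Of these, 60 had at least 5 tested members and were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists. By this test 23 lists were higher and 5 lower in AVM. The other splits of the 8 samples into 4 and 4, which mix the groups, called a median of 20 lists, so a camera call with the preset correlation is weak evidence. With the correlation estimated per list none was called (lowest adjusted p = 0.123, with 12 higher and 0 lower at an unadjusted p under 0.05). The fry test, which asks whether a list's genes move on balance in a single direction, called 7. These were the endothelial, angiogenesis and tip cell, erythroid, interferon response, proliferation, reactive astrocyte and NADPH oxidase lists (fry adjusted p = 0.0206 to 0.0291). A few symbols with no match in the table were left out of their lists. The genes named in the text follow a rule fixed before the data were examined. Its first part takes, among genes past the threshold with a mean CPM of at least 1, a symbol that is no clone name and groups that do not overlap, the 10 with the highest and the 10 with the lowest log2 fold change. Its second part takes up to 4 members with the smallest p in each cell type, state or pathway list. Its last part takes all measured genes of the list for vascular malformation. Only 4 genes fell, so all 4 are named. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen; the sex, blood cell, Ttr, Gapdh and Actb values are quality checks of that kind, as is Adgrl4, the end of a plotted range.

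Samples of a group were compared before averaging: the chi-square of each pair of libraries per degree of freedom lay between 12.4 and 90.8, so no pair agreed within sampling noise. Replicate numbers 1 to 4 occur in both groups, and no label says what they share. Deviations from the group means correlated across genes between same-numbered samples with r = 0.421, 0.142, 0.106 and 0.484, all over 0.1. Between different numbers r ran from -0.484 to 0.367. AVM 2 and AVM 3 correlated better with another number (r = 0.258 with control 4 and 0.322 with control 1), and so did control 2 (0.182 with AVM 4) and control 3 (0.367 with AVM 1). Across the groups, replicates 1 and 3 correlated positively with each other, as did 2 and 4 (0.106 to 0.484). Every correlation between these 2 sets was negative (-0.484 to -0.112). The values thus follow a split of 1 and 3 against 2 and 4 more than a pairing by number. By the bound of 0.1 alone, the numbers were still treated as pairing the samples. The pairing comes from this check and not from a label. The fit with the number as a block is given where it changes a call.

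Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample weights, other low-count filters and robust dispersion. Further ones were limma-trend on log2 of the authors' FPKM with pseudocounts of 1 and 0.1 and with or without a filter at 0.5 FPKM in 4 samples, the replicate block, a 2-fold threshold, an adjusted p of 0.01, 1 surrogate variable (sva 3.50.0) and leaving out each sample in turn. A covariate made from brain region genes, the block combined with the estimated correlation, exchanges within pairs, and leaving out samples in the depth comparison were added after seeing the data. The scripts were tested on simulated counts for AVM against control with the real means and library sizes, a dispersion of 0.0528 and 200 changed genes among 16585 tested. The test recovered 14% of 50 genes changed 1.5-fold, 68% of 50 changed 2-fold, 100% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 12 false calls among 153. In simulated lists of 25 genes, camera recovered 5 of 5 shifted by log2 0.5 among 50, with 0 false calls, but those genes were drawn as independent. Figures were drawn with matplotlib 3.10.9.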

Results

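RNA was sequenced from 8 mouse brain samples, 4 with a brain arteriovenous malformation (AVM) and 4 controls. An arteriovenous malformation is a tangle of vessels in which arteries join veins without a capillary bed between them. The control samples are titled WT1 to WT4 and the others AVM1 to AVM4. If WT stands for wild type, the groups may also differ in genotype, which cannot be told apart from the malformation here. The labels do not say how the malformation was produced, which part of the brain was taken or whether each sample came from its own animal. The p-values therefore measure the spread between these samples. The title of the series sets the question: whether mitochondria passed from astrocytes to vessel-lining cells protect redox balance and the barrier of the malformed vessels. Each library held between 15648866 and 18897075 counts assigned to genes, with a mean of 17038000 ± 1404300 in AVM and 16653000 ± 340660 in control brain (SD, n = 4 each; exact two-sided permutation test, p = 0.686). A single read was worth between 0.0529 and 0.0639 CPM (counts relative to library size), so a gene with no read in a library may stand at up to 0.159 to 0.192 CPM there. The Y-linked gene Ddx3y had 1238 to 1718 counts and Xist 0 to 3 counts in each library, the pattern of male animals in both groups.

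AVM brain differed from control brain mainly by genes that were higher. Of 16508 genes tested, 127 rose and 4 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 against 4), and 108 of the risers and 1 of the fallers changed at least 2-fold. DESeq2 called 331 higher and 46 lower. In all 131 of these genes the AVM and control samples did not overlap; over all tested genes this held for 5.33%, where chance gives 2.86%. The urokinase receptor gene Plaur, which localises plasmin formation at the cell surface (ENSMUSG00000046223; mm10 chromosome 7, 24462484 to 24475968), rose from 0.633 ± 0.126 to 8.04 ± 2.44 CPM (mean ± SD; log2 fold change 3.65 ± 0.28 SE, adjusted p = 0.00196). Hmox1, the haem-degrading enzyme (chromosome 8, 75093621 to 75100589), rose from 3.71 ± 0.928 to 42.6 ± 26.5 CPM (3.52 ± 0.48, adjusted p = 0.0112). The chemokine genes Ccl2 and Ccl12, which attract monocytes, rose by log2 5.10 ± 0.72 and 4.66 ± 0.49 (adjusted p = 0.0143 and 0.00389). Tfpi2, a serine protease inhibitor, rose by 4.95 ± 0.71 (adjusted p = 0.0146), Tgm1, a transglutaminase, by 4.47 ± 0.64 (adjusted p = 0.0146), and Lcn2, an iron-siderophore carrier, by 4.92 ± 0.88 (adjusted p = 0.0426).

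Some of the risers were almost unread in control brain. The elastase gene Mmp12 had no read in any control library and 141 reads over the AVM libraries, which makes it at least 45.9-fold higher against a floor of 3 counts over the control group (adjusted p = 0.036). Hmga2, a chromatin protein of embryonic and growing tissue, had 2 reads over the controls and 233 over the AVM libraries, a ratio of 114 with a counting interval of 31.2 to 946 (95%, Clopper-Pearson; adjusted p = 0.00339). Only 4 genes fell. They were Myoc, the myocilin gene (log2 fold change -1.07 ± 0.16, adjusted p = 0.0177), and the Wnt receptor gene Fzd2 (-0.97 ± 0.14, adjusted p = 0.0177). The others were Prom1, which encodes a protein of membrane protrusions (-0.76 ± 0.14, adjusted p = 0.0417), and Slco1a4, an organic anion transporter of brain vessels (-0.69 ± 0.10, adjusted p = 0.0167). With the replicate number as a block, 81 genes rose, 78 of them in common with the fit without it, and 4 fell, 1 of them in common. Mmp12, Myoc, Fzd2 and Prom1 then had adjusted p = 0.0573, 0.0705, 0.0531 and 0.0719. Leaving out control 1 or control 2 left 48 or 51 risers, and leaving out control 4, AVM 4, AVM 2 or AVM 1 left 69, 77, 79 or 84. The number of fallers was 2 without AVM 2 and 1 without AVM 3 or control 2. It was 0 by edgeR without control 1 or control 3, where 288 and 264 genes were lower at an unadjusted p under 0.05 and DESeq2 on all samples called 46. Of 49 called genes named here or in the closing part, 19 kept their call without control 1 and 21 without control 2. The 18 that kept it with any single sample left out were Hmga2, Ccl12, Plaur, Cdh5, Pecam1, Ly6a, Kdr, Aplnr, Angpt2, Flt4, Col4a1, Col4a2, Tgfb1, Nes, Vim, Serpina3n, Hba-a1 and Tnfaip2. Without control 1 the adjusted p of Lcn2 was 0.154, of Tfpi2 0.084, of Slco1a4 0.0791, of Tgm1 0.0791, of Ccl2 0.0735 and of Hmox1 0.0629.

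**Figure D1:**
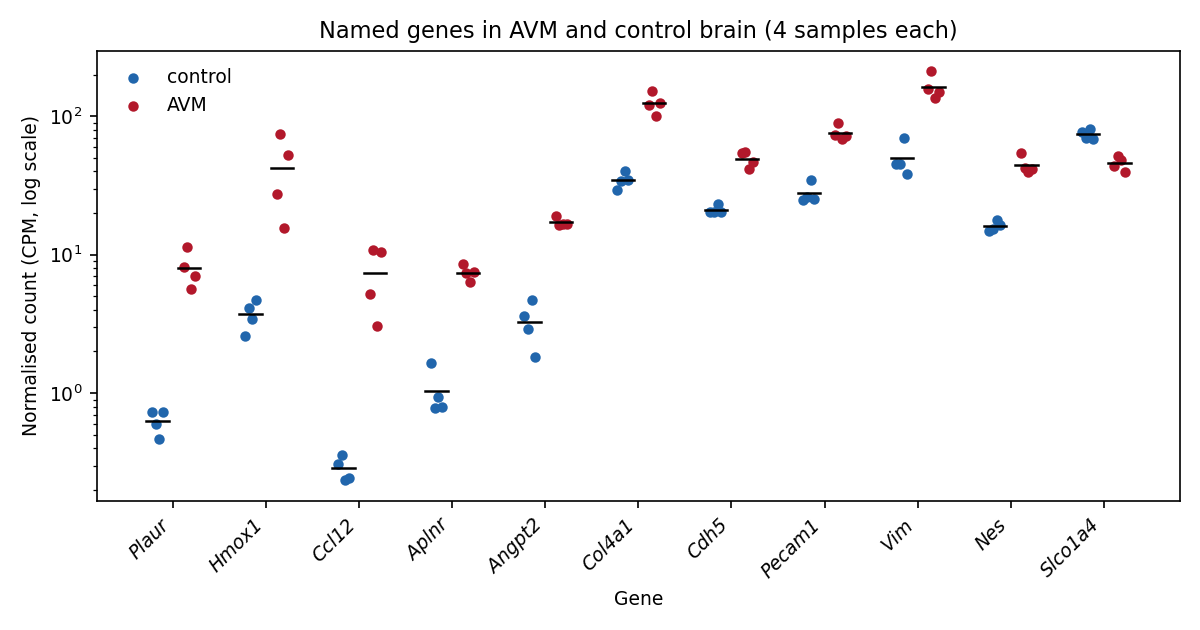
Normalised counts (CPM, log axis) of 11 named genes in each of the 4 control (blue) and 4 AVM (red) samples, with black bars at the group means. The AVM samples lie above all control samples for 10 genes, from Plaur (mean 8.04 against 0.633 CPM) to Nes (44.3 against 16 CPM), and below them for Slco1a4 (45.8 against 74.1 CPM).

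Genes of vessel-lining cells were higher in AVM brain, and genes of sprouting vessels were among the clearest changes. Of the 28 measured endothelial markers 9 rose and 1 fell, with a list median of log2 0.63. Adjusted over the list alone, 19 rose and 2 fell. Cdh5, the adhesion protein of endothelial junctions, rose from 21 ± 1.48 to 49.2 ± 6.28 CPM (log2 fold change 1.23 ± 0.11, adjusted p = 0.0024), and Pecam1, another junctional adhesion protein, from 27.7 ± 4.58 to 75.7 ± 9.20 CPM (1.45 ± 0.13, adjusted p = 0.0024). Kdr, the main receptor for vascular endothelial growth factor, rose by 0.80 ± 0.10 and Ly6a by 0.85 ± 0.11 (adjusted p = 0.01 and 0.00995). The list of angiogenesis and tip cell genes had 9 risers among 30 members (11 adjusted over the list alone; median 0.57). They included Aplnr, the apelin receptor (2.83 ± 0.27, adjusted p = 0.00265). Others were Angpt2, the vessel-destabilising angiopoietin (2.39 ± 0.25, adjusted p = 0.00389), and Flt4, a receptor for lymphatic and angiogenic growth factors (1.43 ± 0.15, adjusted p = 0.00389). Both lists were higher than other genes by camera with a preset correlation (adjusted p = 4.58e-21 and 2.88e-13). Each had adjusted p = 0.123 with an estimated correlation. By fry both were called (adjusted p = 0.0206 each).

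**Figure D2:**
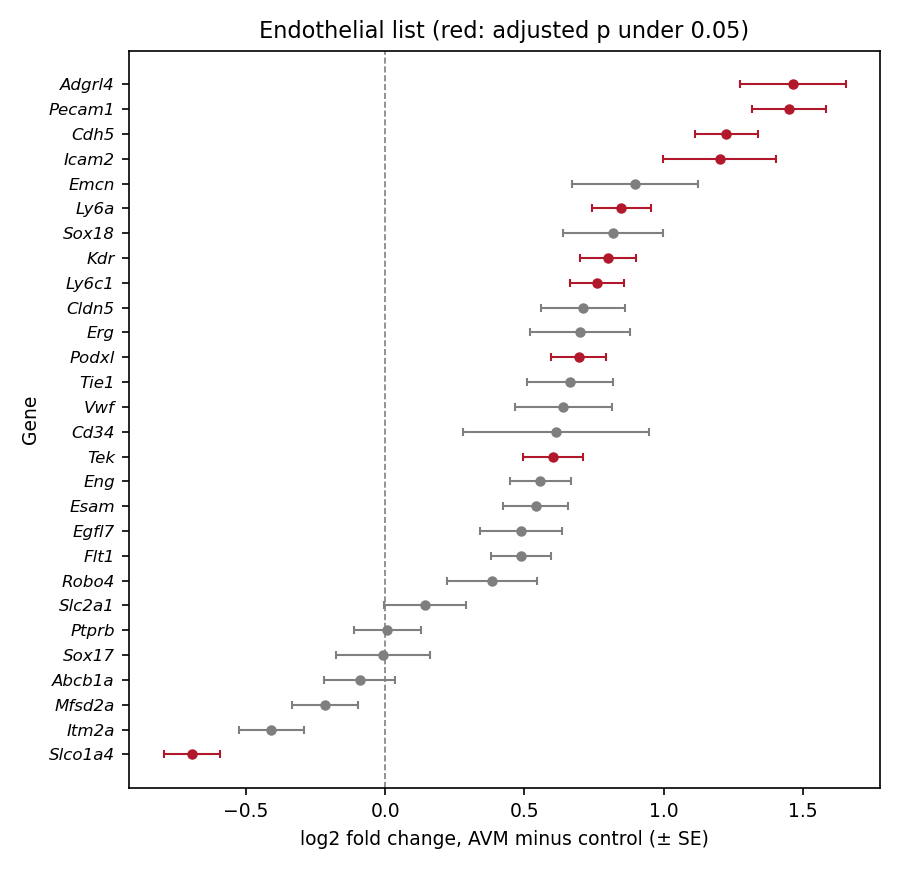
Log2 fold change (AVM minus control) of the 28 measured endothelial markers, with bars of 1 SE and red for genes past an adjusted p of 0.05. Values run from -0.69 for Slco1a4 to 1.46 for Adgrl4.

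Vein, artery and Notch genes moved in small numbers. In the venous list 2 of 10 members, Lcn2 and Sele, rose (5 adjusted over the list alone). Sele, the cytokine-induced adhesion molecule E-selectin, had 1 read over the controls and 113 over the AVM libraries (ratio 110, counting interval 19.4 to 4400, adjusted p = 0.0143). The venous list had camera adjusted p = 0.000153, and adjusted p = 0.198 with an estimated correlation. Of 14 arterial markers only Dll4, a Notch ligand of arterial and tip cells, passed the test (1.43 ± 0.24, adjusted p = 0.0352; 0.0721 with the replicate block; 2 members adjusted over the list alone). The arterial list did not (camera adjusted p = 0.484). In the Notch list 3 of 18 members rose (3 rose and 1 fell adjusted over the list alone). They were Dll4, the ligand Jag1 (1.14 ± 0.15, adjusted p = 0.0103) and the endothelial receptor Notch4 (1.21 ± 0.18, adjusted p = 0.0177). Hes5, a Notch target, stood at -0.88 ± 0.21 (adjusted p = 0.14). The Notch list had camera adjusted p = 0.0221, and adjusted p = 0.329 with an estimated correlation. It was 0.18 without AVM 1, 0.0577 without control 1 and 0.0596 without control 4. With 1 sample left out, the highest adjusted p was 0.155 for Dll4, 0.0893 for Notch4, 0.0805 for Sele and 0.0553 for Jag1. Of 12 mural smooth muscle markers none passed the edgeR test, with 0 up and 2 down at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.2).

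Genes listed beforehand as linked to vascular malformation did not pass the test over all genes. None of the 12 measured members did with edgeR, while DESeq2 called 2 higher and 2 were below an unadjusted p of 0.05. These were Eng and Acvrl1, receptors for bone morphogenetic proteins that are mutated in hereditary haemorrhagic telangiectasia, with log2 fold changes of 0.56 ± 0.11 and 0.59 ± 0.12 (adjusted p = 0.0615 and 0.0665; 0.00399 for both adjusted over the list alone). Mgp stood at -0.64 ± 0.37, Ephb4 at 0.21 ± 0.22, Smad4 at 0.15 ± 0.13, Braf at 0.13 ± 0.16 and Alk at 0.08 ± 0.25. Rasa1 stood at -0.05 ± 0.09, Map2k1 at -0.05 ± 0.14 and Rbpj at -0.06 ± 0.14. None of these 8 passed the threshold. The list itself had camera adjusted p = 0.191. In the BMP and TGF-beta list 2 of 31 members rose (5 rose and 1 fell adjusted over the list alone). Among them was Tgfb1, the growth factor itself, which went from 5.53 ± 1.23 to 19.4 ± 2.05 CPM (1.81 ± 0.18, adjusted p = 0.00304). That list had camera adjusted p = 0.187. In the list of RAS and MAPK targets 3 of 24 members rose (4 adjusted over the list alone; camera adjusted p = 0.0843). They were the ephrin receptor gene Epha2 (1.62 ± 0.24, adjusted p = 0.0177), the membrane protein gene Emp1 (1.70 ± 0.30, adjusted p = 0.038) and the cyclin gene Ccnd1 (1.02 ± 0.18, adjusted p = 0.0384). With the replicate block, Epha2 and Ccnd1 both had adjusted p = 0.0587, and with 1 sample left out the highest adjusted p was 0.0802 for Epha2, 0.123 for Emp1 and 0.16 for Ccnd1.

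Some junction genes of the vessel barrier rose. Of 30 tight junction and barrier genes 2 rose (5 adjusted over the list alone) and the list median was 0.09. The risers were Cdh5 and Lsr, a tricellular junction protein (1.01 ± 0.18, adjusted p = 0.0384; 0.0719 with the replicate block). Cldn5, the main claudin of brain endothelium, went from 45.5 ± 7.85 to 74.4 ± 11.9 CPM without passing over all genes (0.71 ± 0.15, adjusted p = 0.0887; 0.0102 adjusted over the list alone). This list had camera adjusted p = 0.0046 (0.106 without AVM 1), and adjusted p = 0.569 with an estimated correlation. In the extracellular matrix list 6 of 38 members rose (9 adjusted over the list alone). Basement membrane genes were among them, with the type IV collagen genes Col4a1 (34.7 ± 4.46 to 125 ± 21.8 CPM; 1.85 ± 0.15, adjusted p = 0.00196) and Col4a2 (1.45 ± 0.13, adjusted p = 0.0024) and the laminin gene Lamb1 (0.68 ± 0.11, adjusted p = 0.0264; 0.0587 with the block). The matrix list had a median of 0.02, with camera adjusted p = 0.00363 (0.426 without control 4 and 0.0753 without AVM 1), and adjusted p = 0.669 with an estimated correlation. With 1 sample left out, the highest adjusted p was 0.16 for Lsr and 0.103 for Lamb1. None of 14 pericyte markers passed the edgeR test over all genes, against 3 higher by DESeq2, 6 up and 1 down at an unadjusted p under 0.05 and the same numbers adjusted over the list alone. Abcc9 and Rgs5 stood at 0.64 ± 0.13 and 0.55 ± 0.11 (camera adjusted p = 0.000358; adjusted p = 0.402 with an estimated correlation). Of 17 meningeal fibroblast markers 16 lay below 0, with a median of -0.64 (camera adjusted p = 0.000153; adjusted p = 0.6 with an estimated correlation). In that list Col15a1, a vessel-associated collagen, rose (0.89 ± 0.15, adjusted p = 0.0282; 0.0799 with the block and up to 0.114 with 1 sample left out; 1 up and 3 down adjusted over the list alone).

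Mitochondrial gene groups moved little. Reads were summed over all cells of a sample, so these values cannot show whether mitochondria passed from one cell to another. The 13 protein genes of mitochondrial DNA all lay above 0 with a median of log2 0.17, and none passed edgeR or DESeq2 or an unadjusted p of 0.05 (camera adjusted p = 0.0759). Their share of counts, with the rest of the mitochondrial genome, was 5.05% ± 1.10 in AVM and 4.69% ± 0.289 in control brain (SD, n = 4 each; exact two-sided permutation test, p = 0.686). AVM 2 alone reached 6.65%, and without it the AVM mean was below the control mean. Nuclear genes of the respiratory chain were slightly lower as groups. The 36 genes of complex I had a median of -0.08 with 32 below 0, and the 38 genes of complexes II to V a median of -0.08 with 32 below 0 (camera adjusted p = 0.00349 and 0.000864; adjusted p = 0.669 for each with an estimated correlation). Without AVM 3 the adjusted p was 0.0905 for complex I and 0.0771 for complexes II to V, and for complex I it was 0.0891 without AVM 2 and 0.0563 without control 1. None of these 74 genes passed edgeR or DESeq2, and 1, the succinate dehydrogenase gene Sdhb (-0.20 ± 0.07), had an unadjusted p under 0.05. The 26 genes of mitochondrial movement and transfer had a median of -0.05, a mean of 0.02 and camera adjusted p = 0.525. Their 1 riser was Tnfaip2, which promotes tunnelling nanotubes between cells (2.32 ± 0.482 to 6.32 ± 0.554 CPM; 1.44 ± 0.19, adjusted p = 0.0112; also the only member adjusted over the list alone). Mitochondrial dynamics and mitophagy genes (32 members, median -0.02, camera adjusted p = 0.455) and mitochondrial ribosome genes (43 members, median -0.04, camera adjusted p = 0.2) had no member past the edgeR or DESeq2 threshold. At an unadjusted p under 0.05 they had 0 up in either list and 1 and 0 down.

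Antioxidant genes moved little as a group. Genes that make reactive oxygen were higher as a group by camera with a preset correlation, but not with an estimated one. By fry they were higher (adjusted p = 0.0291). In the antioxidant list 1 of 39 members, Hmox1, rose (1 adjusted over the list alone). The median was 0.03 with the camera test pointing down (adjusted p = 0.935). Txnip, an inhibitor of thioredoxin, stood at -0.45 ± 0.12 (adjusted p = 0.187). In the list of NADPH oxidase and other oxygen radical sources 10 of 11 members lay above 0, with a median of 0.82. None of them passed edgeR over all genes, 4 were higher by DESeq2, 8 had an unadjusted p under 0.05 and 6 passed adjusted over the list alone. Cyba and Rac2, subunits or partners of the phagocyte oxidase, stood at 0.85 ± 0.16 and 1.56 ± 0.30 (adjusted p = 0.0511 and 0.0557), and the oxidase gene Nox4 at 2.07 ± 0.49 (adjusted p = 0.136). That list had camera adjusted p = 5.47e-08, and adjusted p = 0.123 with an estimated correlation. The difference between the antioxidant and the radical source lists was not itself tested. In the iron and haem list 2 of 19 members rose, Hmox1 and Lcn2 (4 adjusted over the list alone; camera adjusted p = 0.0192; adjusted p = 0.44 with an estimated correlation). The camera value of this list was 0.111 without AVM 1, 0.0789 without control 1 and 0.0727 without control 4. Of 22 hypoxia response genes 1 rose, the apelin gene Apln (33.2 ± 6.69 to 69.6 ± 5.69 CPM; 1.07 ± 0.14, adjusted p = 0.0103; 2 adjusted over the list alone; camera adjusted p = 0.11). Without control 2 the adjusted p of Apln was 0.0521.

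**Figure D3:**
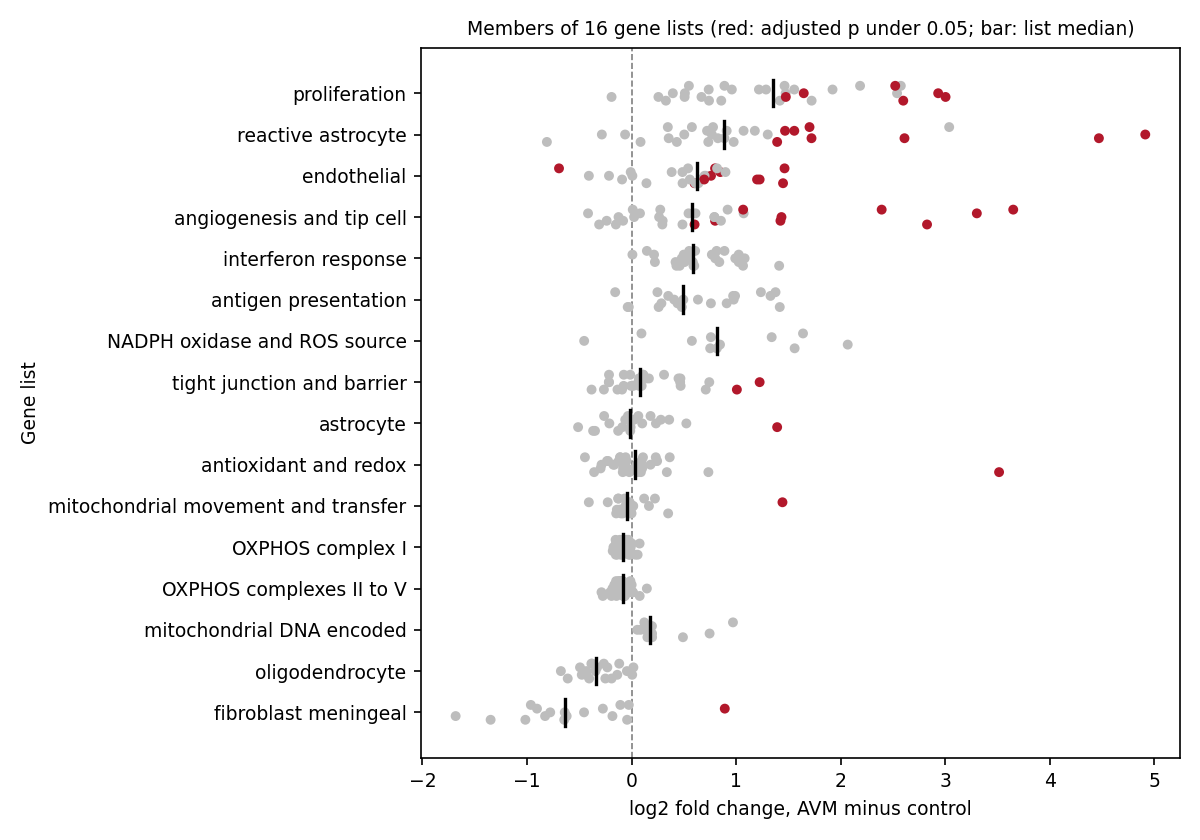
Log2 fold change (AVM minus control) of every measured member of 16 gene lists, 1 point per gene, red where the adjusted p was under 0.05, with a black bar at each list median. Medians run from 1.35 for proliferation to -0.64 for meningeal fibroblast markers, and the respiratory chain lists lie close to 0.

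Astrocyte reactivity and cell division genes were higher in AVM brain. Of 29 reactive astrocyte genes 8 rose (19 rose and 1 fell adjusted over the list alone; median 0.89). Nes and Vim, intermediate filaments of reactive and immature cells, went from 16 ± 1.32 to 44.3 ± 6.86 CPM (1.47 ± 0.13, adjusted p = 0.0024) and from 49.5 ± 13.7 to 164 ± 33.0 CPM (1.72 ± 0.20, adjusted p = 0.00707). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 1.56 ± 0.20 (adjusted p = 0.0103). Vim and Nes are also made by endothelial cells, and Vim stands in the macrophage list too. Of 20 general astrocyte markers only Gfap, the astrocyte filament, rose (302 ± 90.0 to 793 ± 220 CPM; 1.39 ± 0.25, adjusted p = 0.0448; 0.109 with the replicate block; 1 adjusted over the list alone). The median of that list was -0.01 with a camera test pointing up (adjusted p = 0.624). Of 30 proliferation genes 6 rose, 26 rose adjusted over the list alone and 29 lay above 0, with a median of 1.35. The replication helicase gene Mcm3 rose by 1.48 ± 0.20 (adjusted p = 0.0112), Top2a, a topoisomerase of dividing cells, by 3 ± 0.43 (adjusted p = 0.0146), Mki67, the Ki-67 antigen gene, by 2.60 ± 0.40 (adjusted p = 0.0191) and Ube2c by 2.52 ± 0.40 (adjusted p = 0.0243). With the replicate block the last 3 had adjusted p = 0.0613, 0.0531 and 0.0536. With 1 sample left out, the highest adjusted p was 0.181 for Gfap, 0.0992 for Ube2c, 0.0881 for Mki67, 0.063 for Top2a and 0.0589 for Mcm3. The reactive astrocyte and proliferation lists had camera adjusted p = 3.48e-21 and 3.2e-31, and adjusted p = 0.123 each with an estimated correlation. By fry both were called (adjusted p = 0.0217 each).

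Immune genes were higher as groups by camera with a preset correlation, but not with an estimated one. By fry the interferon response list was called (adjusted p = 0.0217). The antigen presentation, cytokine and complement lists were not (fry adjusted p = 0.0698, 0.0689 and 0.148). Few single genes passed the threshold. All 27 interferon response genes lay above 0 (median 0.59). None passed edgeR over all genes, 8 were higher by DESeq2, 15 had an unadjusted p under 0.05 and 13 passed adjusted over the list alone. Ifitm3 and Gbp3, interferon-induced antiviral genes, stood at 1.08 ± 0.21 and 0.89 ± 0.19 (adjusted p = 0.0622 and 0.0903). Of 21 antigen presentation genes, with a median of 0.50, none passed edgeR, 7 were higher by DESeq2, 9 had an unadjusted p under 0.05 and 8 passed adjusted over the list alone. The immunoproteasome gene Psmb8 stood at 0.91 ± 0.18 (adjusted p = 0.0679). Of 20 inflammatory cytokine genes 3 rose, Ccl2, Ccl12 and Sele (13 adjusted over the list alone; median 0.96). Of 18 complement genes 1 rose, C4b (24.9 ± 9.26 to 83.5 ± 12.2 CPM; 1.75 ± 0.25, adjusted p = 0.0143; 6 adjusted over the list alone). Camera adjusted p was 4.42e-20 for interferon response, 9.58e-12 for antigen presentation, 9.49e-11 for cytokines and 1.07e-05 for complement. With an estimated correlation the adjusted p was 0.123, 0.198, 0.198 and 0.301. Homeostatic microglia markers had a median of 0.21 and 0 of 18 past edgeR, with 2 higher by DESeq2, 8 at an unadjusted p under 0.05 and 3 adjusted over the list alone (camera adjusted p = 0.000272; adjusted p = 0.426 with an estimated correlation). Activated microglia markers had 0 of 21 past edgeR, 2 higher by DESeq2, 7 up and 1 down at an unadjusted p under 0.05 and 2 up adjusted over the list alone (median 0.14; camera adjusted p = 0.0161, or 0.0629 without AVM 1; adjusted p = 0.569 with an estimated correlation). Of 13 border and blood macrophage markers only Vim rose (3 adjusted over the list alone; camera adjusted p = 2.84e-05; adjusted p = 0.426 with an estimated correlation). All 6 measured lymphocyte markers lay above 0, with 0 past edgeR or DESeq2 or adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.021, or 0.0727 without AVM 2 and 0.0519 without control 3; adjusted p = 0.198 with an estimated correlation). Without control 1 the adjusted p of C4b was 0.0733.

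Haemoglobin reads moved with these groups. They made up 0.00558% ± 0.00205 of counts in AVM and 0.00055% ± 0.000292 in control brain, 10.2-fold more (SD, n = 4 each; exact two-sided permutation test, p = 0.0286, the smallest that free exchange of the samples allows). With exchanges only within same-numbered pairs p was 0.125, the smallest that test can give. Single libraries ranged from 0.000333% (95% Clopper-Pearson interval 0.00025 to 0.000435%) in control 1 to 0.00812% (0.00768 to 0.00858%) in AVM 2. Hba-a1 rose by 3.20 ± 0.34 (adjusted p = 0.00419), Hbb-bs by 3.49 ± 0.47 (adjusted p = 0.0112) and Hba-a2 by 3.02 ± 0.49 (adjusted p = 0.0283; 0.0531 with the block). Hbb-bt stood at 3.46 ± 0.68 (adjusted p = 0.061). These genes are near-identical pairs whose reads the counting could have split. Of 6 measured erythroid markers 3 rose (4 adjusted over the list alone; camera adjusted p = 1.65e-06; adjusted p = 0.123 with an estimated correlation). With 1 sample left out, the highest adjusted p was 0.123 for Hba-a2 and 0.0605 for Hbb-bs. The neutrophil genes S100a8 and S100a9 had 13 and 36 reads over the AVM libraries against 2 and 8 over the controls. AVM 2 alone held 9 and 25 of them, and 4 and 11 were left without it.

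None of 20 oligodendrocyte markers passed edgeR or DESeq2 or an unadjusted p of 0.05. Of these, 18 lay below 0 with a median of -0.34 (camera adjusted p = 0.00058, or 0.131 without AVM 2 and 0.134 without control 3; adjusted p = 0.669 with an estimated correlation). The myelin gene Mbp stood at -0.61 ± 0.32. General neuron markers had a median of 0.02 with the camera test pointing down (adjusted p = 0.372). Among them 0 of 18 passed edgeR, against 1 lower by DESeq2 and 1 lower at an unadjusted p under 0.05. Brain region markers varied widely inside each group: the choroid plexus gene Ttr ran from 0.941 CPM in AVM 2 to 2390 CPM in AVM 1 and from 106 to 1710 CPM among the controls. A score built from 92 region and choroid plexus genes averaged 1.30 in AVM and -1.30 in control brain (exact two-sided permutation test, p = 0.686, n = 4 each), with AVM 2 highest at 13.8 and AVM 1 lowest at -7.87. The choroid plexus list was lower by camera (adjusted p = 0.0192) but not with the replicate block (adjusted p = 0.107), with an estimated correlation (adjusted p = 0.702) or without AVM 2 (adjusted p = 0.938), AVM 4 (0.11), control 2 (0.165) or control 3 (0.134). With the block, the striatal, hypothalamic and ependymal lists were higher (adjusted p = 0.00668, 0.00357 and 0.00307, against 0.262, 0.624 and 0.445 without it). Each had adjusted p = 0.626 with the block and an estimated correlation.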

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

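The tests on the endothelial and immune genes, and those with the region score, were chosen after the results were seen, and the bound for blood was tightened after its value was seen; the comparison with other splits of the samples and the neurogenic niche markers were fixed before theirs.

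Endothelial genes were higher in AVM brain, but not evenly: once each library was scaled to the mean of the 28 endothelial markers, which rose by log2 0.54, 12 of them still differed between the groups (limma, adjusted over the list alone), 7 below the list mean and 5 above it. The 7 below were Slco1a4 (-1.23), Itm2a (-0.95), Mfsd2a (-0.75), Abcb1a (-0.64), Sox17 (-0.55), Ptprb (-0.53) and Slc2a1 (-0.41), of which Slco1a4, Mfsd2a, Abcb1a and Slc2a1 encode transporters of the blood-brain barrier. The 5 above were Pecam1 (0.91), Adgrl4 (0.88), Cdh5 (0.68), Icam2 (0.66) and Ly6a (0.30); these genes were chosen after their values were seen, and over all genes Icam2 had adjusted p = 0.0342 (0.0753 with the replicate block and up to 0.153 with 1 sample left out) and Adgrl4 0.0103 (up to 0.0548). A larger share of the same endothelial cells alone would raise markers read only from these cells alike. It is argued against as the whole cause to that extent, since whether other cells hold some of the reads was not tested. Centring on the list mean puts members on both sides of it once any differ. With the region score as a covariate 9 of the 9 risers kept their call. The score did not differ clearly between the groups (exact two-sided permutation test, p = 0.686). The kept calls could therefore hardly come out otherwise and do not decide on the region. A larger share together with a shift in endothelial state may account for the pattern and stays open, as a hypothesis, because bulk tissue does not show which cells hold the reads.

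Immune genes were higher as groups, and so was haemoglobin. Below, haemoglobin is summed as CPM of total counts and the immune genes as CPM of TMM library sizes (TMM factors 0.9525 to 1.044). The 86 genes of the interferon, antigen presentation, complement and cytokine lists were higher by 356 CPM in sum, from 1636 ± 134 to 1993 ± 148 (exact two-sided permutation test, p = 0.0286, n = 4 each; 0.125 with exchanges within pairs, the smallest that can give), against 50.3 CPM for haemoglobin, 7.08 times as much (5.98 to 7.58 with 1 AVM library left out). Blood as the whole cause stays open, since reads matching several copies may be missing from haemoglobin: a loss of 85.9% of them would bring the ratio to 1, and Gapdh stood 41.4-fold below the median of 20 other glycolysis genes (74.9-fold without control 4). With the region score as a covariate 39 of the 40 genes that passed within their list kept that call. The score did not differ clearly between the groups (exact two-sided permutation test, p = 0.686), so this could hardly come out otherwise and does not decide on the region. The 4 lists also kept their camera call with a preset correlation. With an estimated one they did not pass even without the score (adjusted p = 0.123, 0.198, 0.301 and 0.198). A larger number of immune cells or a higher activity in them stays open too.

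Proliferation genes were higher, with a median of log2 1.35. Of the 30 list members 6 passed over all genes, and the list had adjusted p = 0.123 by camera with an estimated correlation. More of the neurogenic niche, where adult brain cells divide, would bring neuroblast genes along, but 6 tested markers of it, Dcx and Sox11 among them, had a median of -0.07 and an upper quartile of 0.02, below the lower quartile of the proliferation list (0.69). The niche markers argue against more of that niche as the whole cause. With the region score as a covariate 6 of the 6 called genes kept their call. Since the score did not differ clearly between the groups, this does not decide on other differences in the region taken. Which cells divide may be vascular, glial or immune and was not tested.

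The 8 samples can be split into 4 and 4 in 35 ways, and each was tested. The real split called 127 genes in its larger and 4 in its smaller direction, and 2 of 35 splits, the real one included, gave as many in each case, so by this count chance cannot be excluded for either number. The other split set replicates 1 and 3 of both groups against replicates 2 and 4 and called 416 and 363 genes, several times the real count, which points to a structure of the samples that crosses the groups. That split follows the region score, a measure of brain region content: replicates 1 and 3 held the 4 lowest scores (-7.87 to -2.30) and replicates 2 and 4 the 4 highest (-0.861 to 13.8). With the score as a covariate the real split called 163 higher and 9 lower genes. The other split keeps every pair of same-numbered samples together. Among the 8 splits that part all 4 pairs, the real one included, the real split alone called any gene. The highest other count was 0 in both directions. Exchanges within pairs cannot give a p under 0.125, so this count does not exclude chance either. It also rests on a pairing that no label gives. The correlations between samples followed replicates 1 and 3 against 2 and 4 more than that pairing. The blocked fit called 81 risers. For the gene lists, 7 of 35 splits called at least as many as the real 28 lists. The other splits called a median of 20 lists and at most 34. Chance thus cannot be excluded for the number of camera calls with a preset correlation. Among the 8 splits that part all pairs, 2 called at least as many as the real one, itself included.

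Dixon's ratio picked out samples far from the other 3 of their group in 19 of 292 groups examined, where chance gives about 15. Control 4 had a mitochondrial share of 4.26%, against 4.80 to 4.88% in the other controls. The mean list score (log2, relative to all 8 samples) stood apart for endothelial genes in control 3 at -0.13, for lymphocyte genes in AVM 2 at 0.989, for p53 and cell death genes in control 2 at -0.07 and for general neuron genes in AVM 1 at -0.065. In CPM, control 3 stood apart for Prom1 at 19.9, Cdh5 at 23.2, Pecam1 at 34.5, Rgs5 at 128 and Sele at 0.0588 (a single read). Control 1 stood apart for Hmga2 at 0.123 (its only control library with a read), Lamb1 at 25.7, Psmb8 at 1.90 and Abcc9 at 10.4. AVM 1 stood apart for Angpt2 at 19.1, AVM 2 for Mki67 at 26.8 and Adgrl4 at 85.2, and AVM 3 for Col4a2 at 73.6 and C4b at 65.4.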

How the results depend on the processing

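The region score covariate, the block with the estimated correlation, exchanges within pairs and the depth without single samples were chosen after seeing the data. All 131 called genes kept their sign under every alternative that gave them a value. The number of risers (127) stayed within 1.5 times under 11 other settings (91 to 181) and the region score (163). It was 331 with DESeq2, 41 on the authors' FPKM with no filter, 81 with the replicate block, 33 at an adjusted p under 0.01 and 48 to 114 with single samples left out (fewer samples; lowest without control 1). The number of fallers (4) was 46 with DESeq2, 10 with sample weights, 7 with no low-count filter, 26 with 1 surrogate variable, 9 with the region score, 1 at 2-fold, 0 at an adjusted p under 0.01, 0 on unfiltered FPKM (limma; 600 at an unadjusted p under 0.05) and 0 to 5 with single samples left out. Of 49 called genes named in the text 33 kept their call with the replicate block and 18 with every single sample left out; beyond those given beside the results, the block changed no call of these genes. The block also called the immediate early, oligodendrocyte precursor, circadian clock and cholesterol lists (adjusted p = 0.0475, 0.0382, 0.0382 and 0.0296), but not with an estimated correlation as well (adjusted p = 0.662, 0.626, 0.626 and 0.626). The number of lists called (28) was 0 with an estimated correlation, with or without the block, 7 with fry, and 25 to 34 under the other settings; 15 of 28 lists kept their call with every single sample left out. Where not stated, the cause was not tested. Genes that were not called changed sign in places. With sample weights the log2 fold change of Rasa1 was 0.0112 and the log2 fold change of Alk -0.0065. With single samples left out, the log2 fold change of Braf ran from -0.0166 to 0.2448, of Rasa1 from -0.0793 to 0.011, the log2 fold change of Rbpj from -0.2163 to 0.0233, the log2 fold change of Map2k1 from -0.206 to 0.0261 and of Alk from -0.1785 to 0.2269. The AVM minus control difference in the share of counts from mitochondrial genome genes ran from -0.1729 (without AVM 2) to 0.6229 percentage points, and that in library depth from -234900 (without AVM 1) to 847900 counts. The AVM minus control difference in the share of counts from haemoglobin genes, 0.00503 percentage points, was 0.005334 without the 10 most abundant genes and ran from 0.004182 (without AVM 2) to 0.005715 (without AVM 3) with single samples left out. Its exact permutation p was the smallest possible in each case, 0.0286, or 0.125 with exchanges within pairs, and so does not speak to its stability. At this depth and n, the simulated test found 14% of 1.5-fold changes, so smaller changes were mostly out of reach.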

Other observations

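The test of RAS and MAPK output below was chosen after the result was seen. Oligodendrocyte precursor genes had 0 of 16 members past edgeR over all genes, with 1 lower by DESeq2, 3 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone. These were Gpr17, a receptor of committed precursors, which went from 58.2 ± 5.45 to 36.0 ± 9.44 CPM (log2 fold change -0.69 ± 0.17, adjusted p = 0.16), and Bmp4 (-0.96 ± 0.27, adjusted p = 0.246). The list had camera adjusted p = 0.0618, and 0.0382 with the replicate block; the adjusted p was 0.669 with an estimated correlation and 0.626 with both. Among p53 and cell death genes none of 22 passed edgeR, with 2 higher by DESeq2, 4 up and 1 down at an unadjusted p under 0.05 and 3 up adjusted over the list alone; Eda2r and Ripk3 stood at 1.63 ± 0.34 and 2 ± 0.45 (camera adjusted p = 0.0221, or 0.125 without AVM 2 and 0.0725 without AVM 1; adjusted p = 0.21 with an estimated correlation). Of 24 folding and heat shock genes, with a median of 0.09, none passed edgeR or DESeq2, and 6 up and 1 down had an unadjusted p under 0.05. That list had camera adjusted p = 0.0192 (0.131 without AVM 1), and adjusted p = 0.369 with an estimated correlation. Cytosolic ribosome genes had 0 of 47 past edgeR or DESeq2 and 1 up at an unadjusted p under 0.05 (median 0.06). Their camera adjusted p was 0.0221, and 0.591, 0.218, 0.566 and 0.0925 without AVM 1, AVM 2, control 4 and control 3, and adjusted p = 0.702 with an estimated correlation. Of 16 clock genes none passed edgeR, with 1 lower by DESeq2 and 3 lower at an unadjusted p under 0.05; Per1 stood at -0.84 ± 0.23 (69.2 ± 10.7 against 124 ± 44.1 CPM, adjusted p = 0.22).

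Plaur, Epha2, Emp1 and Ccnd1, which growth factor signalling through RAS and MAPK can induce, were all higher in AVM brain. The hypothesis that this output was higher over the tissue was tested on the list of 24 targets, which holds Epha2, Emp1 and Ccnd1 but not Plaur and whose median was 0.02 and upper quartile 0.25. Its camera adjusted p was 0.0843, and it ran from 0.00266 without control 4 to 0.379 without control 3, so the list does not decide the question. The bound that the upper quartile was set against, and the use of left-out samples to leave the question open, were both chosen after the values were seen. The feedback genes Dusp6, Spry4 and Etv5 stood at -0.02 ± 0.34, -0.04 ± 0.24 and 0.03 ± 0.22 (adjusted p = 0.998, 0.995 and 0.997); they were chosen after their values were seen. A higher output in a small cell population may leave such genes flat in bulk tissue and stays open.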
